A study of Mus musculus with 2 samples.

How the data were processed

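RNA was measured in pieces of small intestine from mice of 2 genotypes, with 1 library each. Per the labels' protocols, the RNA was taken up in TRIzol and the cDNA was amplified by SMART-Seq II, a method that copies full-length polyadenylated transcripts from small amounts of RNA by template switching and PCR. The labels describe no unique molecular identifiers, and whether the libraries kept strand is not given in the sources used here. The deposited table holds FPKM values for 27275 genes, with 1 column per library, in which the authors divided the reads of each gene by its length and by the size of the library. Bowtie2 2.2.3, HTSeq 0.6.0 and the mouse build mm10 are named in the submitters' processing notes, without their roles or order. The annotation release, the read layout, any filter, and whether RNA of several mice was pooled are not given in the sources used here. Mapping and counting settings decide how reads of near-identical gene copies were divided. Values of the Gsdmc, Reg3, Sprr2, Defa, H2, Mcpt and Cyp2c families and of immunoglobulin segments are therefore uncertain for single members. Overlapping and antisense genes could not be separated either, since the strand setting is unknown.

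The group of each library came from its title, and each column of the table was matched to a library by its name. Gene identifiers were joined to GENCODE release M21, whose build GRCm38 is the same assembly as mm10. That annotation held 27222 of the identifiers and lacked 53, and its symbol was equal for 94.4% of the genes in the table. Symbols below are those of the table, and coordinates are those of GENCODE M21, counted from 1. Of the genes in the table, 1854 were listed at 0 in both libraries. The 13479 genes with an FPKM of at least 1 in at least 1 library were compared. The log2 ratio of a gene is log2((knockout FPKM + 1) / (wild-type FPKM + 1)), which understates the difference of genes with low values. Counts of genes at least 2-fold higher or lower use this ratio. Folds are plain ratios of FPKM, without the pseudocount, so a gene with low values can have a fold above 2 and still count as within 2-fold.

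With 1 library per genotype there is no replicate check. No test of the genotypes was made, no p-value is given, and each difference is one between these libraries. Depth was recovered from the values themselves. The product of FPKM and the summed exon length in GENCODE M21 stepped in whole units for 90.5% of the values above 0 in each library, within 0.01 of a whole read. The step size gave a denominator of 17425640 reads for the wild-type library and of 17658566 reads for the knockout library. Whether these totals count mapped reads or reads assigned to genes is not given in the sources used here. Read numbers followed from the exon length for 11842 of the compared genes. For the other 1637 genes, the smallest pair of whole numbers with the observed ratio was used, so that their true read numbers may be larger and their intervals are wide. The recovered reads served for precision only. Intervals of folds are exact Clopper-Pearson intervals at 95% for the share of the reads of a gene that came from the knockout library. They treat each read as an independent draw and leave out the variation between mice. PCR reads without molecular identifiers are not independent molecules, so these intervals can be too narrow even for counting error. A gene at 0 in one library was set to a floor of 3 reads there, and its fold is given against that floor. Such a fold leaves out the counting error of the other library, so the exact interval can begin lower. For a transcript of 1 kb, that floor is 0.172 FPKM in the wild-type library and 0.170 FPKM in the knockout library.

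Before the data were examined, 39 gene lists were fixed for cell types, regions and pathways of the small intestine, together with the comparisons, most of the alternatives and the rule for the genes that the text names. Of the genes on the lists, 29 were not analysed here because neither their symbols nor a synonym matched a gene of the table. For each list the median log2 ratio of its compared members was taken with its binomial 95% interval. That interval is set by ranked members of the list, treats genes as independent draws and does not cover variation between mice. Over all compared genes the median log2 ratio was -0.049, so an interval that spans 0 is only a description. The median of each list was ranked among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes how the list stands apart in these libraries and is not a test of genotype. Lists with fewer than 5 compared members have values only. The named genes are Spib, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes of at least 5 FPKM in at least 1 library, and members of the lists. Predicted or unnamed loci, antigen receptor segments, ribosomal protein genes, names with -ps, small RNAs and mitochondrially encoded genes were left out of the 12 at each end, which left 6901 genes to choose from. From a list, the text may name the 2 members written first and the 4 with the largest absolute log2 ratio. Genes named outside this rule are said to have been chosen after their values were seen.

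The alternatives were pseudocounts of 0.1 and 5, no filter on low values or a minimum of 5 FPKM, scaling to equal sums (as TPM), to equal medians, to equal upper quartiles or without the 20 most abundant genes of each library, thresholds of 1.5-fold and 4-fold, protein-coding genes only, list members on no other list, random lists not matched on expression, and summed FPKM of a list. Chosen after seeing the data were leaving out antigen receptor genes, a minimum of 10 reads, and removal of the trend of the log2 ratio on GC content and exon length, which could be computed for 13473 of the compared genes. The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

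The procedure was tested on simulated data: reads of 27222 genes were drawn for the knockout library against the wild-type library at their recovered depths, with 200 genes set 3-fold or 8-fold higher or lower. The read numbers of 100% of the genes were recovered, and for genes given a wrong length the true reads were a whole multiple of the recovered pair in 99.8% of cases. The simulated values were made with the same exon lengths that served to recover the reads. Both figures therefore check the calculation only and not the recovery in the deposited values, where the exon length gave the reads of 87.9% of the compared genes. The changed genes were drawn only from genes with a mean of at least 5 FPKM and a minimum exon length. Among them, all simulated 3-fold higher, 98% of those 3-fold lower and all simulated 8-fold higher or lower were counted as at least 2-fold. The share that would be counted among genes with lower values was not simulated. Of 13071 unchanged genes, 96 passed 2-fold by counting error alone, which is 0.734%. The fold intervals held the true ratio for 95.8% of the genes examined, with reads drawn independently. Of lists made of unchanged genes, 6% fell outside the 2.5 and 97.5 percentiles. All lists drawn from the changed genes set 3-fold higher, which had a mean of at least 5 FPKM, lay above them.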

Results

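The libraries were made from small intestine of mice that lack Spib in the gut epithelium and of mice labelled wild type, to ask how the intestinal transcriptome of naive animals differs without this factor. Spib encodes an ETS family transcription factor that epithelial M cells need for their development and that B cells and plasmacytoid dendritic cells also express. In the knockout, the floxed gene is removed by Cre recombinase driven by the villin promoter, which is active in intestinal epithelium and not in immune cells. The genotype label of the wild-type library also names Villin-Cre. The design text describes the tissue as proximal small intestine. There was 1 library per genotype, at implied depths of 17425640 reads for the wild type and 17658566 reads for the knockout. An FPKM of at least 1 was reached by 13007 genes in the wild-type library and by 12726 in the knockout library. The 20 most abundant genes held 24.0% of the FPKM sum in the wild-type library and 26.8% in the knockout library. No value below has a replicate. The intervals beside folds cover counting error only, as if each read were an independent molecule.

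Spib was lower in the knockout library. The gene (ENSMUSG00000008193, minus strand of chromosome 7, 44525993 to 44532071, mm10) had an FPKM of 4.94 in the wild-type library, from 247 reads, and of 0.592 in the knockout library, from 30 reads. That is 8.34-fold lower, with a counting interval of 5.70 to 12.6, and a log2 ratio of -1.90. The log2 ratio was -0.83 with a pseudocount of 5, no longer past 2-fold, and -2.86 with a pseudocount of 0.1. The direction went with the labels. The values are sums over the exons of the gene, and which exons were floxed is not given in the sources used here. B cell genes were lower as well, with a list median of -0.80 that includes Spib. Without Spib the summed FPKM of that list was 2.12-fold lower, a smaller difference than the 8.34-fold of Spib. The part of the difference that lies in the epithelium could not be separated in whole tissue.

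Most genes differed little between the libraries, and 12924 of the 13479 genes compared, or 95.9%, lay within 2-fold. At least 2-fold higher in the knockout library were 217 genes, and at least 2-fold lower were 338. Antigen receptor segments and constant regions made up 135 of the lower genes and 14 of the higher. Protein-coding genes numbered 97 in each direction. Fewer than 10 recovered reads in both libraries were found for 87 of the higher and 104 of the lower genes. Both counts can be too high, since genes with the smallest whole pair may have more reads. With a pseudocount of 0.1 the counts were 355 higher and 575 lower, and with a pseudocount of 5 they were 61 and 122.

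The gene with the highest log2 ratio was Pla2g4c, which encodes a cytosolic phospholipase A2 (chromosome 7, 13324655 to 13360672). Its FPKM was 3.54 in the wild-type library and 924 in the knockout library, 261-fold higher with a counting interval of 229 to 298. Mptx1, a pentraxin gene of Paneth cells, had 1.44 against 88.2 FPKM, and Sprr2a3, a small proline-rich protein of the epithelial barrier, had 5.31 against 89.2, while the 3 Sprr2 genes measured, which can share reads, summed to 22.1 and 129.8 FPKM. The neighbouring gasdermin C genes of chromosome 15 (63824346 to 63912297) were higher together. Gsdmc4 had 46.4 against 438 FPKM, Gsdmc2 had 28.1 against 215 and Gsdmc3 had 10.8 against 88.4. These copies are closely related and can share reads, and the 4 measured members of the family summed to 86.5 FPKM in the wild-type library and 754 in the knockout library, 8.72-fold higher. Reg4, a secreted lectin of enteroendocrine and secretory cells, was 8.59-fold higher (8.10 to 9.12), and Duoxa2, the maturation factor of the epithelial hydrogen peroxide source DUOX2, was 7.92-fold higher (7.33 to 8.56). The pancreatic lipase relative Pnliprp2 was 7.64-fold higher (7.19 to 8.12), malic enzyme Me1 was 10.1-fold higher (8.95 to 11.5) and carbonic anhydrase Car1 was 18.2-fold higher (11.5 to 30.6). The remaining gene of the 12, U90926, had 0.933 against 13.8 FPKM.

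The lowest log2 ratios among the 6901 genes ranked, which leave out antigen receptor segments, were those of Reg3g, Saa1, Reg3b and Nos2. Reg3g, a lectin that kills Gram-positive bacteria (minus strand of chromosome 6, 78466269 to 78468872), had 2329.5 FPKM in the wild-type library and 76.9 in the knockout library, 30.3-fold lower with a counting interval of 29.2 to 31.4. Its neighbour Reg3b was the third most abundant gene of the wild-type library, at 8421 FPKM, and had 618 in the knockout library, 13.6-fold lower (13.4 to 13.9). Reg3d, in the same cluster, had 6.31 against 0.652 FPKM. The 4 Reg3 genes measured summed to 10857 FPKM and 735 FPKM. The acute-phase gene Saa1 was 23.7-fold lower (18.7 to 30.5), Nos2, the inducible nitric oxide synthase, 16.3-fold lower (13.7 to 19.6), and Ubd, the ubiquitin-like modifier FAT10, 11.3-fold lower (7.18 to 18.9). Socs3, a feedback inhibitor of STAT3 signalling, had 38.4 against 9.42 FPKM, and Tifa, an adaptor of NF-kB signalling, had 73.0 against 15.7. The rest of the 12 were the galactosyltransferase B3galt5 at 21.7-fold lower, the secreted phospholipase Pla2g5 at 10.1-fold, tyrosine aminotransferase Tat at 9.67-fold and the membrane protein gene Mal at 6.50-fold.

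**Figure D1:**
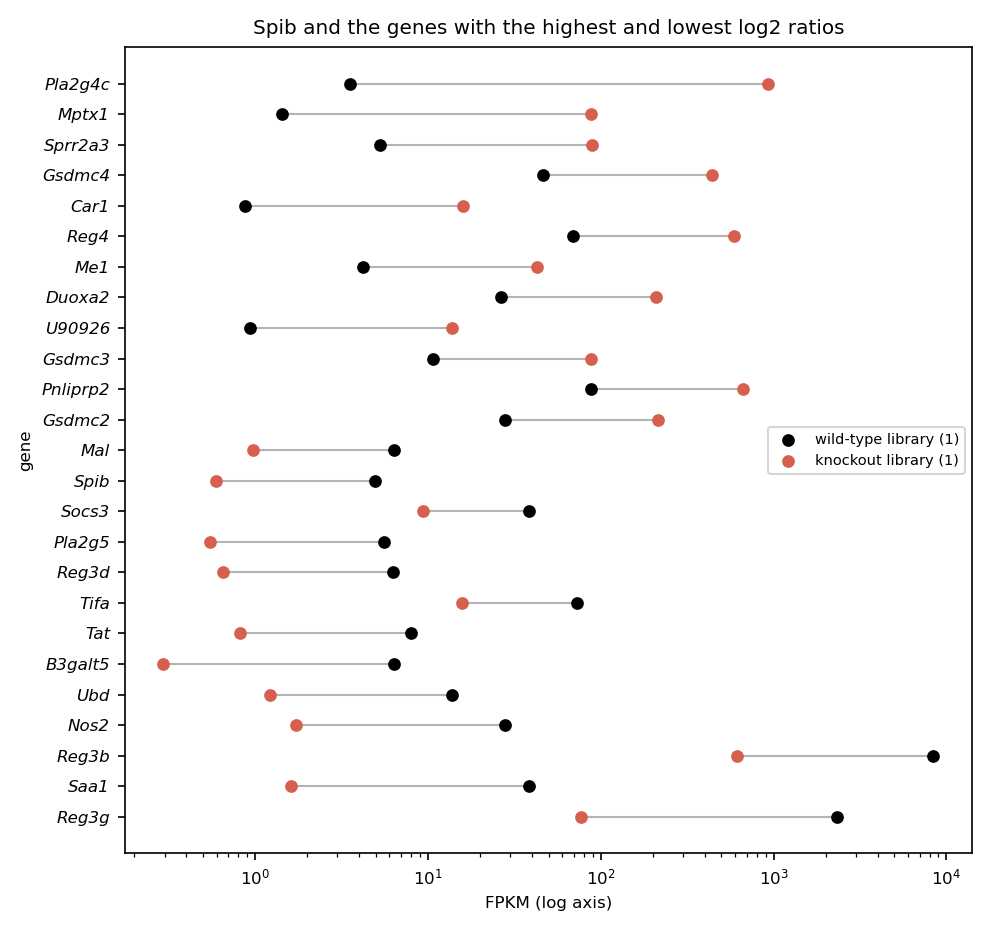
FPKM of Spib and of the 12 genes at each end of the log2 ratio, on a log axis, with the wild-type library in black and the knockout library in red; each point is 1 library and the line joins the values of a gene. Pla2g4c spans 3.54 to 924 FPKM, and Reg3g spans 2329.5 to 76.9 FPKM in the other direction.

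Of the 37 gene lists with at least 5 compared members, 11 had a median above the central 95% of their random lists, 14 lay below it and 12 lay within. The percentiles alone would place 1.85 lists outside. For 8 of the lists outside, the binomial interval of the median spans 0: M cell, Paneth cell, fatty acid oxidation, proximal, defence, eosinophil and mast cell, type 3 and immediate early genes. Genes of a list can vary together from one piece of tissue to the next, which random lists do not contain, so these numbers describe the libraries and not the genotypes.

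Tuft cell genes were higher in the knockout library. Tuft cells are chemosensory epithelial cells that release interleukin-25. The median log2 ratio of 33 genes was 0.88, above the medians of all 10000 random lists. At least 2-fold higher were 15 of them, none was 2-fold lower and 18 lay between. Of the 33 genes, 4 are also on another list. The microtubule-associated kinase Dclk1 had 1.144 against 4.81 FPKM, 4.21-fold higher (3.71 to 4.78). The taste transduction channel Trpm5 had 1.39 against 6.96, 5.004-fold higher (4.21 to 5.98), and gustducin Gnat3 had 0.548 against 4.49. Rgs13, a regulator of G-protein signalling, was 6.83-fold higher (5.51 to 8.54), Sh2d6 was 5.49-fold higher (3.92 to 7.85) and the lineage factor Pou2f3 was 3.76-fold higher (2.68 to 5.396). Beside these values, mitochondrially encoded genes were higher and lymphocyte genes were lower in the same library, by the medians given further on. The tuft cell median was 1.53 with a pseudocount of 0.1 and 0.49 with a pseudocount of 5, since most of its genes were below 10 FPKM.

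Genes of type 2 immunity and some genes of the eosinophil and mast cell list were higher as well, at low levels. The type 2 list had a median log2 ratio of 0.45 over 16 genes, above all 10000 random lists, with 3 genes at least 2-fold higher, none 2-fold lower and 13 between. Besides Sprr2a3, the eosinophil chemokine Ccl24 had 0.886 against 4.07 FPKM and the interleukin-33 receptor Il1rl1 had 1.71 against 4.96, 2.89-fold higher (2.47 to 3.41). Interleukin-13 (Il13) had 0 reads in the wild-type library and 11 in the knockout library, 3.62-fold higher against the floor of 3 reads. Il33 itself had 13.7 against 14.6 FPKM. Among genes of at least 5 FPKM the list lay at the 92.4 percentile and no longer stood apart, and its median was 0.22 without a filter on low values and 0.18 with a pseudocount of 5. The eosinophil and mast cell list had a median of 0.71 over 7 genes, above all random lists. Those were the ones compared of its 20 genes measured. At least 2-fold higher were 3 genes, Siglecf, Mcpt1 and Mcpt2, and 4 lay between. Values of single members of the Mcpt family are uncertain. The binomial interval of the list median, -0.51 to 1.93, spans 0, and the median was 0.16 without a filter on low values. Siglecf, which tuft cells also express, was 5.98-fold higher (4.57 to 7.94) and the mucosal mast cell protease Mcpt1 was 5.03-fold higher (3.42 to 7.59). The eosinophil peroxidase gene Epx was near the floor, with 2 and 3 reads.

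Secretory lineages differed in some of their products. The goblet cell median was 0.30 over 20 genes, above all random lists, with 3 genes at least 2-fold higher and 17 between. The calcium-activated chloride channel regulator Clca1 had 696 against 2059 FPKM, 2.96-fold higher (2.93 to 2.99), and Spink4 had 511 against 1095. The gel-forming mucin Muc2 had 199 against 237 and trefoil factor Tff3 had 1793 against 1849.9. The Paneth cell median was 0.28 over 21 genes (binomial interval -0.17 to 0.89, which spans 0; summed FPKM 0.44 as a log2 ratio), above 9999 of the random lists, with 5 genes 2-fold higher, none 2-fold lower and 16 between. The ribonuclease gene Ang4 had 809 against 4221 FPKM, 5.22-fold higher (5.11 to 5.33), and colipase Clps had 151 against 345. Lysozyme Lyz1 was lower, at 5754 against 4250.3, and the defensin-processing protease Mmp7 had 132 against 151. The 26 alpha-defensin genes and pseudogenes measured, whose copies share reads, summed to 26916 FPKM in the wild-type library and 35457 in the knockout library. At least 2-fold higher were 3 of them, and as many were 2-fold lower. Enteroendocrine genes had a median of -0.04 at the 57.0 percentile, with 1 of 20 genes 2-fold higher and 19 between. Chga had 24.1 against 16.6 FPKM. The summed FPKM of that list was higher in the knockout library, with a log2 ratio of 1.199, since it holds Reg4.

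Lymphocyte and antigen presentation genes were lower in the knockout library. The list of MHC class II and antigen presentation had a median of -0.89, with 8 of 20 genes at least 2-fold lower, none higher and 12 between. The invariant chain Cd74 had 310.2 against 108 FPKM, 2.88-fold lower (2.75 to 3.01), H2-Ab1 had 167 against 63.8, and the class II transactivator Ciita had 5.17 against 2.29. The B cell list, which includes Spib, had a median of -0.80, with 6 of 20 genes 2-fold lower and 14 between. The antigen receptor component Cd79a was 2.57-fold lower (2.01 to 3.32) and the follicle chemokine Cxcl13 was 2.47-fold lower (1.81 to 3.39). In the plasma cell list the median was -0.69, with 7 of 19 genes 2-fold lower and 12 between. The constant regions Igkc and Igha had 1039.7 against 213 FPKM and 655 against 151, and the joining chain Jchain had 181 against 57.8. T cell and intraepithelial lymphocyte genes had a median of -0.61, with 5 of 20 genes 2-fold lower and 15 between. Ccl5 was 3.92-fold lower (3.01 to 5.18), the T cell receptor constant region Trac 3.60-fold lower (2.11 to 6.46) and granzyme Gzmb 2.51-fold lower (2.08 to 3.03). These 4 lists lay below all 10000 random lists. The medians of B cell, plasma cell and T cell genes were -1.33, -1.46 and -0.96 with a pseudocount of 0.1. With a pseudocount of 5 they were -0.30, -0.30 and -0.27, and that of MHC class II was -0.51.

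The lists of macrophages and dendritic cells, innate lymphoid cells, interferon response and epithelial defence had medians below 0 as well. The macrophage and dendritic cell list had a median of -0.33, below all random lists, with 1 of 23 genes 2-fold lower. That gene was Ccr7, the receptor with which dendritic cells migrate to lymph nodes, at 2.35 against 0.544 FPKM. Csf1r had 15.8 against 13.0 FPKM. The list of type 3 and innate lymphoid genes had a median of -0.27 over 8 genes, at the 2.1 percentile, and its only gene past 2-fold was Ltb, with 4.62 against 1.61 FPKM. With a pseudocount of 5 that list lay at the 3.51 percentile, within the central 95%, and the macrophage and dendritic cell median was -0.15. Interleukin-22 (Il22), which induces Reg3 genes in epithelium, had 8 reads in the wild-type library and 0 in the knockout library, 2.70-fold lower against the floor. Interferon response genes had a median of -0.44 over 38 genes, below all random lists, with 3 genes 2-fold lower, none higher and 35 between. Zbp1 was 3.19-fold lower (2.70 to 3.78) and the GTPase Igtp 2.87-fold lower (2.44 to 3.39). The summed FPKM of these 38 genes was nearly equal in the libraries, with a log2 ratio of -0.024, and the median was -0.23 with a pseudocount of 5. The list of antimicrobial and epithelial defence genes had a median of -0.30, also below all random lists, with 6 of 21 genes 2-fold lower, 3 higher and 12 between. Reg3g, Reg3b, Saa1 and Nos2 were among the lower ones, and Reg4 and Duoxa2 were among the higher. The binomial interval of the median, -1.33 to 0.13, spans 0, and the summed FPKM of the list had a log2 ratio of -1.01.

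**Figure D2:**
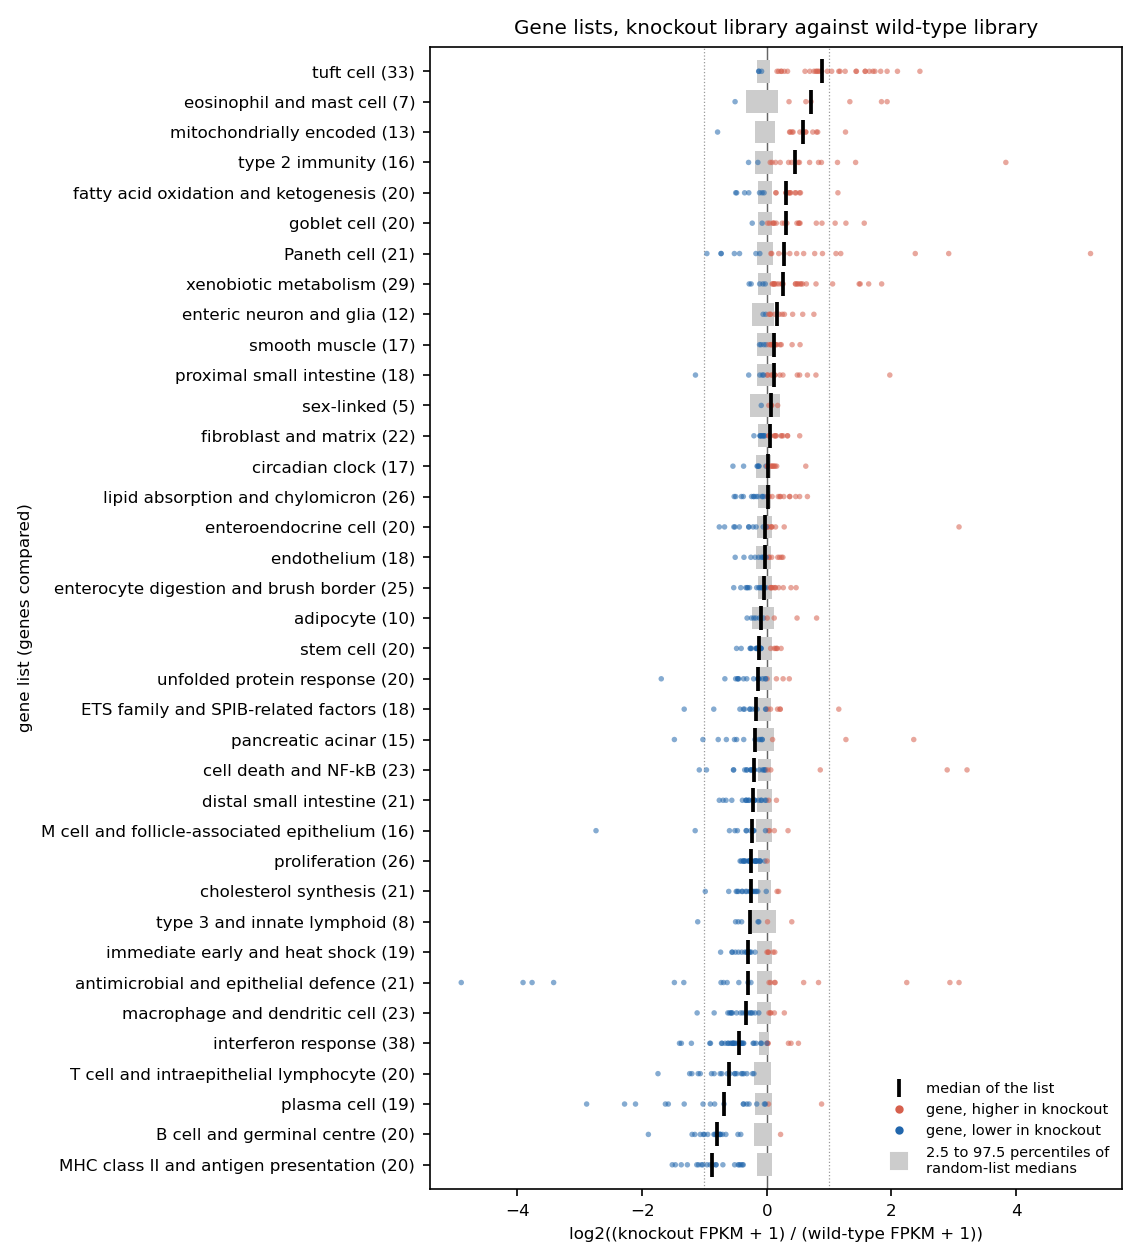
Log2 ratios of the genes in each of the 37 lists, 1 point per gene, with the knockout library over the wild-type library on the horizontal axis; black bars are list medians, grey boxes span the central 95% of the medians of 10000 random lists, and dotted lines mark 2-fold. The tuft cell median lies highest at 0.88 and that of MHC class II and antigen presentation lowest at -0.89, while the enterocyte median of -0.04 lies inside its box.

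Gp2, a receptor of mature M cells, was below 1 FPKM in both libraries, with 31 reads in the wild-type library and 1 in the knockout library, a 31.4-fold difference with a counting interval of 5.24 to 1280.3. Gp2 is also on the pancreatic acinar list, of whose 15 compared genes 12 had log2 ratios below 0 and 3 above. The median of the acinar list was -0.19 at the 5.6 percentile, with 2 genes 2-fold higher and 2 lower. Its summed FPKM had a log2 ratio of -0.03. These differences are small beside that of Gp2. Without members on another list, the acinar median was -0.28 at the 1.51 percentile. The acinar list therefore does not settle which cells gave the Gp2 reads, and their cell type could not be told in whole tissue. The list of M cell and follicle-associated epithelium had a median of -0.24 over 16 genes, at the 0.34 percentile, with 2 genes 2-fold lower and 14 between. Those past 2-fold were Ubd and clusterin Clu, at 14.0 against 5.78 FPKM, and neither is restricted to M cells. Genes of B cells and follicles were lower in the same library, with the list median of -0.80 and the Cxcl13 fold of 2.47 given above. Tnfaip2 had 3.12 against 2.27. The summed FPKM of the list went the other way, with a log2 ratio of 0.12. Its most abundant gene Serpinb1a, chosen for mention after its values were seen, had 327 against 415 FPKM.

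Absorptive, stromal and muscle genes lay close to 0. The list of enterocyte digestion and brush border had a median of -0.04 over 25 genes (binomial interval -0.13 to 0.08), at the 50.8 percentile, and no gene reached 2-fold. Villin Vil1 had 924 against 856 FPKM, and sucrase-isomaltase Sis had 868 against 1203. Lipid absorption genes had a median of 0.01 over 26 genes at the 82.2 percentile, with Apob at 446 against 520 FPKM. Stem cell genes had a median of -0.12 over 20 genes at the 10.98 percentile, and Lgr5 had 2.21 against 2.01 FPKM. Proliferation genes had a median of -0.25, below 9999 of the random lists, although none of the 26 reached 2-fold. Mki67 had 29.95 against 26.8 FPKM, and with a pseudocount of 5 the median was -0.16. The medians of fibroblast and endothelium genes were 0.05 over 22 genes at the 93.0 percentile and -0.04 over 18 genes at the 60.1 percentile. The smooth muscle median was 0.11 over 17 genes at the 98.1 percentile, with Actg2 at 78.6 against 114 FPKM, and without a filter on low values it lay at 97.35, within the central 95%.

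Genes that mark positions along the intestine were compared to see how alike the sampled positions were. Distal genes had a median of -0.23 over 21 genes at the 0.12 percentile, and proximal genes had a median of 0.11 over 18 genes at the 98.9 percentile. No distal gene reached 2-fold. Among proximal genes the calcium-binding S100g was 4.18-fold higher (3.34 to 5.27) and the iron exporter Slc40a1 2.57-fold lower (2.32 to 2.84), and 16 lay between. Without members that are on another list, the proximal list lay at the 96.3 percentile and no longer stood apart, while its median was 0.19 with the trend on GC content and length removed and its summed FPKM had a log2 ratio of 0.48. Although the design text calls the tissue proximal, the ileal bile acid genes were abundant in both libraries. Fabp6 had 2030.2 against 1735 FPKM and Slc10a2 had 92.6 against 92.1. The duodenal factor Pdx1 had 4 reads in the wild-type library and 1 in the knockout library, and was chosen for mention after its value was seen.

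Mitochondrial and xenobiotic genes were higher in the knockout library. Transcripts of the mitochondrial genome had a median of 0.59 over 13 genes, above all random lists, with 1 gene 2-fold higher and 12 between. With mitochondrial ribosomal and transfer RNAs included, mitochondrially encoded genes made up 7.65% of the FPKM sum in the wild-type library and 10.01% in the knockout library. The cytochrome oxidase subunit mt-Co1 was the most abundant gene of the wild-type library at 12238 FPKM, against 15777. The xenobiotic metabolism list had a median of 0.26, above all random lists, with 5 of 29 genes 2-fold higher and 24 between. The glutathione transferase Gstm3 was 3.75-fold higher (3.34 to 4.22), the cytochrome P450 Cyp1a1, a target of the aryl hydrocarbon receptor, 3.90-fold higher (3.04 to 5.05) and Cyp2c66 3.83-fold higher (3.06 to 4.82).

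Immunoglobulin V segments, the variable parts of antibody genes, differed from one segment to the next. With at least 10 reads in 1 of the libraries there were 139 of them, of which 105 were at least 2-fold lower in the knockout library, 9 at least 2-fold higher and 25 between. Their FPKM summed to 3631 in the wild-type library and 1282 in the knockout library, 2.83-fold lower. Segments named here were chosen after their values were seen. Ighv3-1 had 3.44 against 77.3 FPKM, 22.5-fold higher (14.5 to 36.6), Ighv10-1 had 9.27 against 134.6, 14.5-fold higher (11.1 to 19.3), and Igkv19-93 had 8.22 against 53.8. Igkv10-94 had 94.8 against 0.490 FPKM, and Ighv1-81 had 175 against 1.94. The most abundant segment of the wild-type library, Igkv1-135, held 6.02% of its V segment FPKM, and that of the knockout library, Iglv1, held 11.6%.

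**Figure D3:**
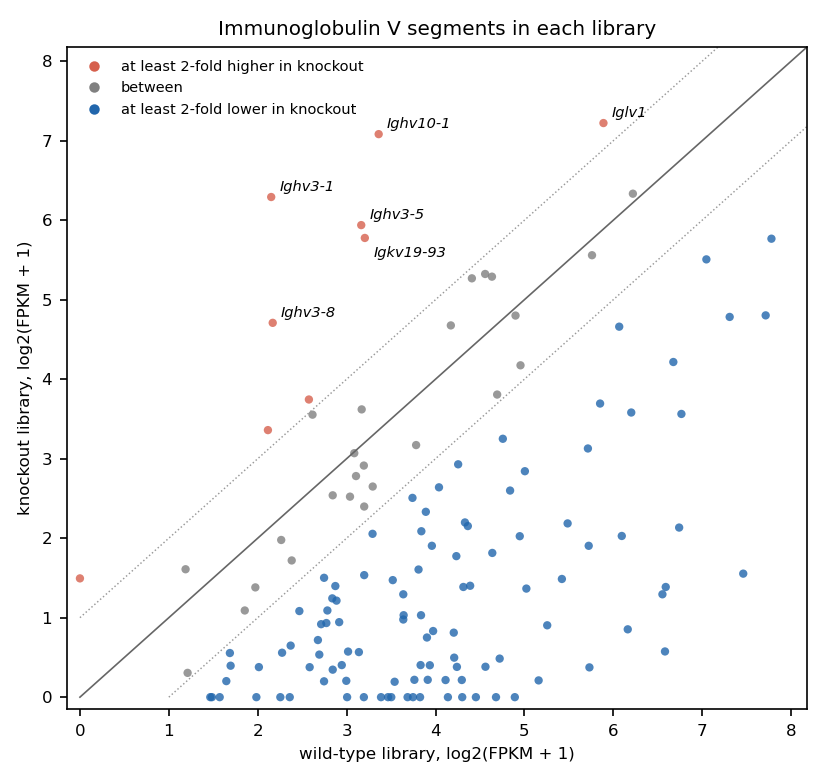
Immunoglobulin V segments with at least 10 reads in 1 of the libraries, 1 point per segment, as log2(FPKM + 1) in the wild-type library (horizontal) and the knockout library (vertical); the solid line marks equality and the dotted lines 2-fold. Below the lines lie 105 segments, and 9 lie above them, including Ighv3-1 and Ighv10-1.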

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

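Leaving out a replicate was not possible with 1 library per genotype. No paired analysis was possible because the labels pair no libraries and each genotype has 1. Tests chosen after seeing the data were those without antigen receptor genes, with at least 10 reads, and with the GC content and length trend removed. The Spib log2 ratio was -2.86 with a pseudocount of 0.1 and -0.83 with 5, and stayed inside its counting interval under the 4 scalings. The number of higher genes was 355 and 61 with these pseudocounts, 97 with at least 5 FPKM, 480 and 37 at 1.5-fold and 4-fold, 97 among protein-coding genes and 130 with at least 10 recovered reads. The number of lower genes was 575 and 122 with the pseudocounts, 193 with at least 5 FPKM, 767 and 106 at the other thresholds, 97 among protein-coding genes and 203 without antigen receptor genes. These follow from the stricter or looser criterion. List medians kept their direction for all lists outside the percentiles except under summed FPKM, where the M cell list gave 0.12 and the cell death list 0.78. The largest differences in FPKM were those of Serpinb1a in the former and of Gsdmc4 and Gsdmc2 in the latter. Summed FPKM also gave -0.024 for interferon response, -1.14 for B cell, -1.65 for plasma cell and -1.13 for T cell genes. With a pseudocount of 0.1 the medians were 1.53 for tuft cell, -0.61 for interferon, -1.33 for B cell and -0.96 for T cell genes. With a pseudocount of 5 they were 0.49 for tuft cell, -0.16 for proliferation, -0.51 for MHC class II, -0.23 for interferon, -0.30 for B cell, -0.27 for T cell and -0.15 for macrophage genes. The B cell median was -1.07 with at least 5 FPKM and -0.72 with the GC and length trend removed, and the smooth muscle median was 0.16 when centred on the median of all genes. Of 440 medians under alternatives, 415 stayed inside the binomial interval of their list. For lists outside the central 95%, 21 of 276 such medians still moved by over 1.5 times. With a pseudocount of 0.1 these were 1.10 for eosinophil and mast cell and -1.46 for plasma cell genes. With 5 they were 0.45 and -0.30 for these, 0.18 for type 2, -0.13 for type 3 and 0.070 for neuron and glia genes. With at least 5 FPKM they were -0.37 for plasma cell, 0.11 for type 2 and -0.52 for macrophage genes, and without a filter 0.22 for type 2 and 0.16 for eosinophil and mast cell genes. Removing the GC and length trend gave 0.19 for proximal and -0.10 for cell death genes. Summed FPKM gave 0.44 for Paneth cell, 0.14 for fatty acid oxidation, 0.48 for proximal, -1.01 for defence, 0.79 for type 2, 1.53 for eosinophil and mast cell and -0.10 for immediate early genes. Of 440 percentiles, 428 kept their side of the central 95%, and the others were of the proximal, type 2, type 3, smooth muscle, pancreatic acinar, unfolded protein response and ETS lists. Causes of shifts other than those named were not tested. For genes near 1 FPKM, depth limits what can be seen, since 1 read on a transcript of 1 kb is worth 0.0574 FPKM in the wild-type library.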

Other observations

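Metabolic and stress programmes outside the comparisons above differed by less than 2-fold for most genes. Fatty acid oxidation and ketogenesis genes had a median log2 ratio of 0.31 over 20 genes, above all 10000 random lists, with a binomial interval of -0.07 to 0.38 that spans 0 and a log2 ratio of 0.14 for their summed FPKM. Cpt1a was at 36.4 FPKM in the wild-type library and 50.2 in the knockout library. Cholesterol synthesis genes lay the other way, at -0.26 over 21 genes and below 9999 random lists, with squalene epoxidase Sqle at 24.3 against 15.6 FPKM. Immediate early and heat shock genes had a median of -0.29 over 19 genes, below all random lists, with a binomial interval of -0.45 to 0.0033 that spans 0 and a log2 ratio of -0.10 for their summed FPKM, and with Fos at 64.3 against 48.4 FPKM. In the unfolded protein response list the median was -0.14 at the 3.1 percentile, with 1 of 20 genes, Chac1, 5.19-fold lower (3.56 to 7.78). Its chaperone Hspa5 had 231 against 232 FPKM. The cell death and NF-kB list had a median of -0.20 over 23 genes at the 0.24 percentile, with Casp4 2.44-fold lower (2.09 to 2.86), 2 genes 2-fold higher and 20 between. Those 2 were Gsdmc4 and Gsdmc2, and with them the summed FPKM of the list was higher in the knockout library.

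Other lists served as checks on the tissue. ETS family and SPIB-related factors had a median of -0.17 over 18 genes at the 3.3 percentile, with the B cell coactivator Pou2af1 3.17-fold lower (2.53 to 4.001), Pou2f3 2-fold or more higher and Spi1 at 2.79 against 2.23 FPKM. Enteric neuron and glia genes had a median of 0.17 over 12 genes at the 99.2 percentile, none past 2-fold by the log2 ratio. Among them Chat, which tuft cells also express, had 0.225 against 1.07 FPKM. Pancreatic acinar genes had a median of -0.19 over 15 genes at the 5.6 percentile, with 2 genes 2-fold higher, 2 lower and 11 between. Pnliprp1 had 1.81 against 13.4 FPKM and Cpa1 had 1.05 against 0.194. The adipocyte median was -0.09 over 10 genes at the 36.6 percentile, the circadian median 0.02 over 17 genes at the 84.5 percentile, and the sex-linked median 0.07 over 5 genes at the 82.6 percentile, with Xist at 60.7 against 63.9 FPKM. Erythroid and neutrophil lists had too few compared genes for a percentile. Hbb-bs had 4.41 against 3.83 FPKM, and S100a8 had 3 reads in the wild-type library and 0 in the knockout library.

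For the patterns below, the tests of GC content and length were set out after the other data were seen and before their own results, and all other tests, as well as the mention of Ighm and of single V segments, were chosen after the results were seen.

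Tuft cell genes were higher in the knockout library. A larger share of epithelium in that piece would raise enterocyte genes as well, which is argued against by their median of -0.038, with a binomial interval up to 0.08. Removing the trend on GC content and exon length left the tuft cell median at 0.96, which argues against such a bias as the whole cause. A different position along the intestine cannot be told apart, since the distal median of -0.23 and the proximal median of 0.11, or 0.48 as summed FPKM, leave a shift open and no value here gives tuft cell levels by position. A difference between the mice other than genotype, such as colonisation by organisms that tuft cells sense, may also account for the pattern and cannot be told apart from the knockout with 1 library per genotype.

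Lymphocyte and antigen presentation genes were lower, and so were Reg3b, Reg3g, Saa1 and Nos2. Less lymphoid tissue in the knockout piece, for example fewer Peyer's patch or follicle cells, may account for the lymphocyte part. The B cell median of -0.80 does not test this, since it is part of the pattern itself. None of the 20 B cell genes is on another list, and the most abundant, Ighm and Cd79a, had 28.8 against 16.5 and 9.10 against 3.54 FPKM. As summed FPKM the log2 ratios were -1.14 for B cell, -1.65 for plasma cell and -1.13 for T cell genes. The difference was thus not largest for B cell genes, and fewer follicle cells could not be told apart from fewer lymphocytes of all kinds. The smooth muscle, fibroblast and endothelium medians lay no further than 0.11 from 0. For the 4 defence genes, removing the trend on GC content and length left the log2 ratio closest to 0 at -3.32, which argues against such a bias as the whole cause. Whether less lymphoid tissue also lies behind them cannot be told apart: their smallest fold of 13.6 exceeds the 2.12 of the summed B cell list without Spib, but they were picked as the lowest genes and lymphoid cells can act on epithelial genes. Whether the knockout itself, other mice or a chance piece of tissue set either part stays open.

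Immunoglobulin V segments went both ways, with 9 segments at least 2-fold higher. Of the 24 families with at least 2 segments, 19 were at least 2-fold lower as a whole, 3 lay between and 2 were at least 2-fold higher. The 2 were Ighv10 (5.70-fold, 4.88 to 6.68) and Iglv (2.23-fold, 2.004 to 2.49). These values argue against an even loss over the families in these libraries. Whether families differ as much between mice of the same genotype cannot be told with 1 library per genotype. A move of counted reads between the measured segments of Ighv10 and Iglv, which were picked as higher, is argued against. Ighv10-1 had 795 more reads in the knockout library, while the family's other segment had 133 in the wild-type library and 250 in the knockout library. Iglv1 had 627 more, while the other 2 had 93 and 84. Reads that the unknown mapping and counting settings dropped or placed elsewhere cannot be seen here. The other higher segments lie in families where sharing of reads stays open. The families of Igkv1-133, Igkv4-70 and Igkv13-84 were lower by 1.51-fold or more, which sharing allows. Most families were lower, however, so such a total does not separate sharing from a rise of 1 segment. Sharing cannot be told apart either for Ighv3-1, Ighv3-5 and Ighv3-8, whose family had a fold of 1.12 (1.03 to 1.21). The same holds for Igkv19-93, whose family has 1 segment. A different set of antibody clones in each animal is a candidate explanation that was not tested, and with 1 library per genotype it stands beside genotype and the choice of tissue piece.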
